A study of Mus musculus with 6 samples.

How the data were processed

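Libraries were made from total RNA, extracted with a column kit, by a strand-specific messenger RNA protocol and sequenced, per the labels' protocols. Alignment used TopHat2 on the mouse genome build mm9, per the submitters' processing notes, which give no version, and the gene annotation is not given in the sources used here. The single table of the series has the layout of a Cuffdiff gene comparison, per the file headers, with WT as the first and KO as the second condition. Its 2 value columns hold FPKM, 1 per condition, computed by the authors over replicates, and the sources used here do not say which libraries entered each condition or how libraries were scaled to each other. The log2 fold change of KO over WT, the test statistic (a score), the p-value and the q-value are the authors' own, per the file headers. Of 18162 rows with both values above 0, the deposited log2 fold change differed from log2 of KO over WT by more than 0.0001 in 8. The deposited q-value equalled a Benjamini-Hochberg adjustment over the 14095 tested genes to within 5.18e-07, and the smallest deposited p-value was 5e-05, shared by 3418 called genes, so such genes cannot be ranked by it. Positions are those of the table (mm9). Where genes overlap the table gives the joined region, which holds for 5179 rows, and 101 rows name more than 1 gene, so values of overlapping genes are uncertain.

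With only the authors' comparison at hand, no test of gene expression was run anew, and genes were called at the deposited q under 0.05 and split by the sign of the deposited fold change, as set for such a table before the data were examined. The 56 tested genes that are listed at 0 in 1 condition have no finite fold change and were left out of medians, and 4 of them are called. For a gene list, the median log2 fold change was compared with 10000 random lists that had as many genes in each of 10 classes by mean FPKM, which gives a two-sided permutation p-value, adjusted by Benjamini-Hochberg over 26 lists. This p-value treats genes as independent and takes no account of replicates, so it describes these pooled values. Of 27 lists fixed before the data were examined, the genes encoded by the mitochondrial genome were not analysed here. Called members were compared with other tested genes by Fisher's exact test, and the deposited p-values of a list were also adjusted over the list alone. Chromosomes were compared in the same manner. Calls lower against higher were compared by an exact binomial test.

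A second matching, added after the data were seen, used 100 classes formed from 5 bins by level, 4 by transcript length and 5 by GC content. Length and GC content came from the longest GENCODE M21 transcript with the gene's symbol or synonym, found for 13985 tested genes (99.2%), and only names, lengths and base content were taken from that annotation, which is on another build. For equal totals, the log2 ratio of the KO to the WT sum of FPKM over tested genes was subtracted from each log2 fold change, with the calls kept. Windows of 30, 60 and 100 neighbouring genes were set against 100 shuffles of gene positions, and gene families were formed from symbol roots with at least 20 tested genes; all 3 were added after the data were seen. The other alternatives, fixed in advance, were q under 0.01 or 0.1, a fold threshold of 2, recomputed adjustment, a filter at the 25th percentile of level, 1 row per symbol, means in place of medians, a pseudocount of 1, recentring on abundant genes, and 1 gene per run of called neighbours within 1 Mb.

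The genes named in the text follow a rule written before the data were examined. It takes Alkbh1, Pou5f1, Sox2 and Nanog, the 6 highest and the 6 lowest called fold changes at or above the median level among genes with a regular symbol, up to 2 called members per list with the smallest q (ties by larger fold change), and 2 called X-linked genes in each direction. List members named only because their count was 5 or fewer, the neighbours of Alkbh1, and the genes named for the chromosome 1 segment were chosen after their values were seen. A list among those compared, with a gene that the rule picks from it, is not reported here.

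The list test was tested on simulated data before use, in 20 tables of 14039 genes that kept the trend with level and had residuals shuffled. A shift of 0.5 put into lists came back as 0.49 on average. Of 280 shifted lists, 79.6% had an unadjusted permutation p-value under 0.05 in the direction put in, as had 7.08% of 240 unshifted lists in either direction. A shift of -0.1 put into the X genes came back as -0.097, with an unadjusted permutation p-value under 0.05 in 80% of tables. X genes without a shift were not simulated. Shuffling also removes any likeness between neighbouring genes, so these shares do not hold for the adjusted calls on real genes. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.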

Results

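Messenger RNA of mouse embryonic stem (ES) cells with and without a knockout (KO) of Alkbh1 was sequenced, to find which genes differ between the genotypes. Alkbh1 encodes a dioxygenase of the AlkB family, enzymes that remove methyl groups from nucleic acids. The cells were of the TT2 line, with a mixed C57BL6 and CBA background, at passage 5 and grown without feeder cells. The series held 6 libraries, of which 2 were wild type (WT) and 4 were KO, the KO libraries coming from 2 clones with 2 libraries each. Gene values were deposited as 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments) for WT and 1 for KO, beside the authors' fold change, test statistic, p and q. No library had a value of its own in that table, so the levels below carry no SD, the clones could not be compared, and the sequencing depth is unknown. Each q rests on the spread that the authors' program estimated, and the labels do not say whether the replicates were separate cultures. Since the KO libraries came from 2 clones, no call below can separate an effect of the genotype from differences between cell clones. The authors' deposited table held 23951 genes, of which 14095 were tested and 9850 were not. The test failed for 5 genes, which were Nanog, Nr6a1, Zfp281, Mir181a-2 and Mir181b-2. The elongation factor gene Eef1a1 was marked as having too many reads, and its KO value, listed at 0, is not a measurement.

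The targeted gene was lower in KO but did not pass the threshold. In the authors' deposited table, Alkbh1 (chromosome 12, 88769027 to 88813249, mm9, a region that the table gives alike for 5 overlapping genes) stood at 33.9 FPKM in WT and 18.1 FPKM in KO, which is 53.4% of the WT level, with a log2 fold change of -0.90 and q = 0.0943. Genes of similar level were also lower, with a median log2 fold change of -0.34 over the 1404 genes in the same decile by level, and 10.2% of them lay below Alkbh1. In the authors' deposited table, 2 neighbours that share this region, Snw1 at -0.96 and Slirp at -1.05, were called lower. The labels do not state which part of Alkbh1 was deleted, and a gene-level value also counts transcript outside a deleted part, so the value by itself neither identifies nor excludes a knockout allele.

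A large part of the tested genes differed between the genotypes by the authors' test, and the direction followed expression level. At q under 0.05 the authors' deposited table called 7163 genes, 50.8% of those tested, with 3163 higher and 4000 lower in KO. The lower genes made up 55.8% of the calls (exact two-sided binomial p = 5e-23, a description, since genes are not independent). Among called genes with at least a 2-fold difference this turned, with 1274 higher and 756 lower. Across the tested genes the median log2 fold change fell from 0.69 in the lowest decile by level (mean of 0.24 to 0.69 FPKM) to -0.72 in the highest decile (mean above 76.1 FPKM). Spearman's rho between fold change and level was -0.55 across genes, which are not independent replicates. Genes at or above the median level of 7.57 FPKM had a median of -0.37. The gene lists below are given both as measured and against random lists matched by decile of level. The highest decile is wide, from 76.1 to 24029 FPKM with a median of 164 FPKM. Its most abundant genes are thus compared mostly with less abundant ones. Within deciles by level, the called genes split into 3704 above and 3455 below the median of their decile. The FPKM of tested genes summed to 981679 in WT and 624340 in KO (63.6%), and the falls as measured depend on the scaling. That ratio alone does not show a difference in scaling, since a shift of reads to longer transcripts also lowers such a sum. Fold changes rose with transcript length (Spearman's rho 0.30 across genes), from a median of -0.46 in the shortest decile to 0.44 in the longest. With equal totals, a choice made after the data were seen, every log2 fold change would be 0.65 higher, the same 7163 calls would split into 4788 above and 2375 below 0, and Pou5f1 and Sox2, given below as measured, would stand at -0.12 and -0.11. The medians given below for primed epiblast, FGF and ERK, BMP, Nodal and TGF-beta, and X-linked germline lists would then be 0.02, 0.10, 0.08 and 0.03. Differences from level-matched lists stay the same under any single factor if the level classes are kept. Classes formed from rescaled values were not tried.

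**Figure D1:**
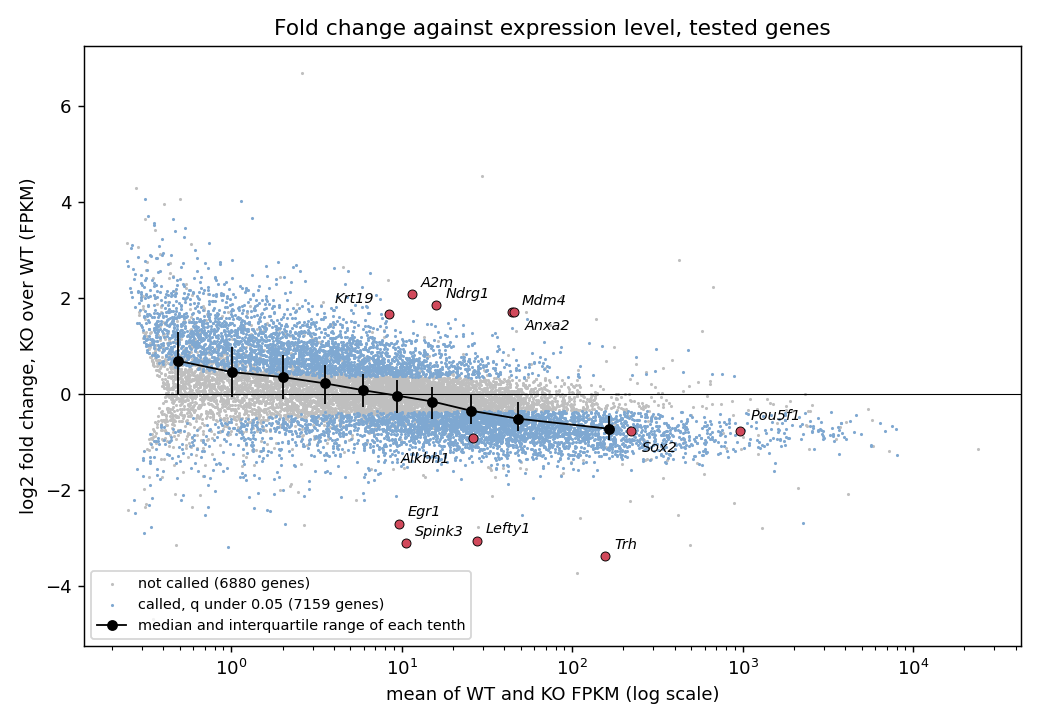
Each point is 1 tested gene with a finite fold change, with the mean of its WT and KO FPKM on a log axis and its log2 fold change (KO over WT) on the other axis; blue points are the 7159 called at q under 0.05. Black points are the medians of the deciles by level with their interquartile ranges, which run from 0.69 to -0.72, and red points are genes named in the text, with Pou5f1 and Sox2 close to the median of the highest decile and Trh and Lefty1 far below it.

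The genes that fell furthest among those of at least median level included secreted regulators and an immediate early gene. Per the authors' deposited table, Trh, which encodes thyrotropin-releasing hormone, fell from 286 to 27.6 FPKM, a 10.3-fold difference. Spink3, a serine protease inhibitor gene, fell 8.57-fold to 2.23 FPKM, and Lefty1, a secreted antagonist of Nodal signalling, from 49.2 to 5.94 FPKM in the authors' deposited table. Egr1, an immediate early gene of ERK signalling, fell from 16.7 to 2.58 FPKM in the authors' deposited table. Rps27rt was also among the 6, at 3931 FPKM in WT and 611 FPKM in KO in the authors' deposited table, but it is a near-identical copy of a ribosomal protein gene, so its reads are uncertain. The last of the 6, the microRNA gene Mirlet7d, was listed in the authors' deposited table at 23.4 FPKM in WT and at 0 in KO, and the values of such short genes are uncertain in messenger RNA libraries.

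The genes that rose furthest at such levels included protease inhibitor, cytoskeletal and p53 pathway genes. In the authors' deposited table, the protease inhibitor gene A2m rose 4.25-fold, from 4.37 to 18.6 FPKM, and Ndrg1, a hypoxia-responsive gene, rose 3.61-fold, from 6.93 to 25.02 FPKM. Anxa2, which encodes a calcium-dependent membrane-binding protein, rose from 21.3 to 70.0 FPKM, and Mdm4, which encodes an inhibitor of p53, from 20.7 to 68.2 FPKM in the authors' deposited table. The epithelial keratin gene Krt19 rose 3.19-fold to 12.8 FPKM in the authors' deposited table. The small nucleolar RNA gene Snora30 was listed there at 0 in WT and 18.3 FPKM in KO, with the same doubt as for Mirlet7d.

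Pluripotency genes were mostly lower as measured, yet not lower than level-matched lists. Of the 29 tested genes of naive and core pluripotency, 16 were called lower, 3 higher and 10 not called, and the same counts came out when adjusted over the list alone. In the authors' deposited table, Pou5f1 fell from 1222 to 716 FPKM (log2 fold change -0.77) and Sox2 from 278 to 164 FPKM (-0.76). Nanog stood at 481 FPKM in WT and 426 FPKM in KO in the authors' deposited table, with a failed test. The orphan receptor gene Nr0b1 (-1.40) and the zinc finger gene Sall4 (-1.28) led the fall, while Tfcp2l1 (0.71), Tbx3 (0.69) and Klf5 (0.58) rose in the authors' deposited table. The list's median was -0.50, while random lists matched on level averaged -0.55 (permutation p = 0.603, adjusted p = 0.802), so the fall as measured turns into a difference of 0.05 above level-matched lists. The highest decile spans 76.1 to 24029 FPKM. Matching by decile therefore cannot compare very abundant genes such as Pou5f1 with genes of their own level.

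Genes of the primed or formative epiblast, the state that follows naive pluripotency, were lower on both scales. Of 14 tested, 10 were called lower and none higher, and 11 were lower and 1 higher when adjusted over the list alone. The list members Fgf5 and Sox3 were not tested. Uncalled were Otx2, Lef1 and Tead2, which lay below 0, and Cd24a at 0.34. The forkhead gene Foxd3 fell from 5.34 to 2.18 FPKM and the zinc finger gene Zic2 from 22.4 to 10.7 FPKM in the authors' deposited table. The median of -0.63 lay 0.60 below that of level-matched lists (permutation p = 0.0019, adjusted p = 0.00988). The adjusted p was 0.0644 when only members at or above the 25th percentile of level were used, and ranged from 0.00195 to 0.0644 over the alternatives.

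FGF and ERK targets and genes of the BMP, Nodal and TGF-beta pathway fell more often than they rose, and WNT targets did not. Of 19 tested FGF and ERK pathway targets, 12 were called lower and 3 higher (Ier3, Spred2 and Etv5), and 12 and 4 when adjusted over the list alone. Beside Egr1, the proto-oncogene Myc fell from 14.6 to 5.16 FPKM in the authors' deposited table. The list's median of -0.55 lay 0.49 below level-matched lists (permutation p = 0.0032, adjusted p = 0.0139). Of 21 tested genes of the BMP, Nodal and TGF-beta pathway, 11 were lower and 3 higher (Bmp4, Bmp7 and Acvr1), and 12 and 3 when adjusted over the list alone. Lefty2, which like Lefty1 is a target and antagonist of Nodal signalling, fell from 86.3 to 15.1 FPKM in the authors' deposited table. That list's median of -0.58 lay 0.51 below level-matched lists (permutation p = 0.0052, adjusted p = 0.0193), with adjusted p from 0.00195 to 0.228 over the alternatives, of which the filter on low genes and the added pseudocount (0.0637) ended the call. Of 11 tested WNT targets, 3 rose (Axin2, Apcdd1 and Nkd1) and 3 fell (Myc, Notum and Ccnd1), the same when adjusted over the list alone, and the median of 0.04 did not differ from level-matched lists (permutation p = 0.767, adjusted p = 0.867).

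Hypoxia and glycolysis genes rose against the general fall of abundant genes. Of 29 tested, 19 were called higher, 1 lower (Higd1a) and 9 not called, with the same counts when adjusted over the list alone. In the authors' deposited table, Ndrg1 rose as above, and P4ha2, a subunit of collagen prolyl hydroxylase, rose from 7.92 to 21.97 FPKM. The median was 0.49 as measured and 1.003 above that of level-matched lists (permutation p = 0.0001, the smallest that 10000 random lists can give, adjusted p = 0.0009).

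Targets of p53 were higher on both scales. Of 25 tested, 9 were called higher, 3 lower (Aen, Trp53 and Bax) and 13 not called, likewise when adjusted over the list alone. Trp53 encodes p53 itself, and the list fixed in advance held it with the targets. In the authors' deposited table, Btg2, an antiproliferative gene, rose from 11.2 to 25.8 FPKM and Trp53inp1 from 24.5 to 49.3 FPKM. The median of 0.27 lay 0.49 above level-matched lists (permutation p = 0.0004, adjusted p = 0.0026). Btg2, like Mdm4 above, lies in a segment of chromosome 1 in which 36 of 60 genes were called higher and 7 lower. That segment was picked for its high median after the data were seen, so a high count of higher calls follows from that choice. Without Btg2 the list's difference was 0.48 (permutation p = 0.0013, adjusted p = 0.00845, with a range from 0.0009 to 0.00845).

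Markers of other cell types did not move one way. Of 12 tested neuroectoderm genes, 6 were lower and 3 higher (Ncam1, Map2 and Msi1), and 6 and 4 when adjusted over the list alone. Pax6, a transcription factor gene of the eye and neural tube, fell from 3.58 to 0.552 FPKM and Sox11 from 2.81 to 0.910 FPKM in the authors' deposited table. The list's median of -0.31 lay 0.67 below level-matched lists (permutation p = 0.012, adjusted p = 0.039), but not with the least expressed members left out (adjusted p = 0.787, with a range from 0.0039 to 0.787). After recentring on abundant genes its median was 0.06. Of 16 tested endoderm genes, 9 were higher, such as the collagen gene Col4a2, and 2 lower (Sox7 and Dab2). Of 18 trophoblast genes, 7 were higher, including Esx1 and Tead4, and 3 lower (Gata3, Fgfr2 and Ascl2). Of 9 mesoderm genes, 3 were higher (Hand1, Mesp2 and Eomes) and 1 lower (Twist1). Of 15 fibroblast markers, which would mark feeder cells, 8 were higher, led by Pdgfrb at 0.318 FPKM in WT and 0.895 FPKM in KO in the authors' deposited table, and 2 were lower (Acta2 and Vim, the latter falling from 61.4 to 21.99 FPKM). Adjusted over the list alone, the counts were the same for the endoderm, mesoderm and fibroblast lists, and trophoblast had 8 higher. These 4 lists had medians of 0.51, 0.41, 0.49 and 0.74, which did not pass against level-matched lists (permutation p from 0.099 to 0.961, adjusted p from 0.232 to 0.961). Without matching on level, called higher genes were more frequent in the endoderm list (odds ratio 4.45, Fisher's exact adjusted p = 0.0179) and in the fibroblast list (3.96, adjusted p = 0.0255) than among other tested genes.

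**Figure D2:**
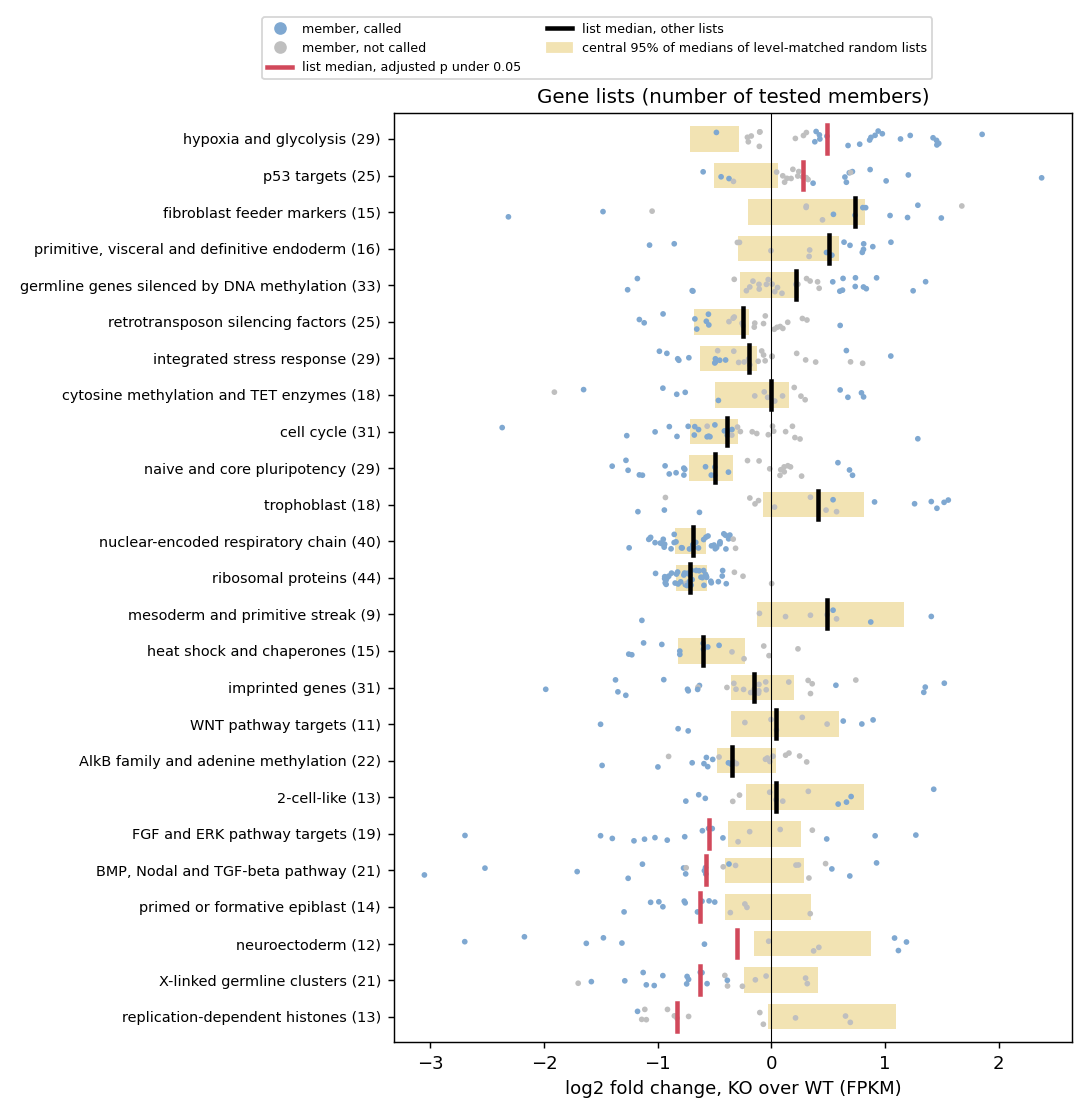
Rows are the gene lists with tested members that the text reports, ordered by their median's distance from level-matched lists, with the number of tested members in brackets. Points are members (blue where called), vertical bars are list medians of the log2 fold change (KO over WT), and shaded spans hold the central 95% of medians of 10000 level-matched random lists; the 8 medians in red passed an adjusted p of 0.05, with hypoxia and glycolysis at the top and histones at the bottom.

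Lists of germline and of 2-cell-like genes were compared next. Of 21 tested genes of X-linked germline clusters (Rhox, Xlr and Mage families), 13 were called lower and none higher, and 14 were lower when adjusted over the list alone. The homeobox genes Rhox8 and Rhox6 fell from 10.5 to 3.49 FPKM and from 36.0 to 14.7 FPKM in the authors' deposited table, where reads of near-identical cluster members are uncertain. The median of -0.63 lay 0.71 below level-matched lists (permutation p = 0.0001, the smallest possible, adjusted p = 0.0009), and matching also on transcript length and GC content ended the call (adjusted p = 0.0895, with a range from 0.0009 to 0.0895). Of 33 tested germline genes that DNA methylation silences in other tissues, 11 were higher and 4 lower (Tdrd12, Rpl10l, Hormad1 and Sycp3), the same when adjusted over the list alone. Tex13 rose from 0.707 to 1.81 FPKM, while Tdrd12 fell from 91.6 to 38.1 FPKM in the authors' deposited table. The median of 0.22 did not pass against level-matched lists (permutation p = 0.0696, adjusted p = 0.201), but did after matching on length and GC content as well (adjusted p = 0.0052, with a range from 0.0052 to 0.351). Of 13 tested 2-cell-like genes, which mark a rare totipotent-like state, 4 were higher (Sp110, Usp17le, Tmem92 and Zfp365) and 3 lower (Eif1a, Zscan4a and Zscan4c), the same when adjusted over the list alone (permutation p = 0.34, adjusted p = 0.53 for the median of 0.04).

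Imprinted genes showed single large differences. Of 31 tested imprinted genes, 9 were lower and 4 higher (Igf2r, Peg3, Zim1 and Sgce), the same when adjusted over the list alone. The growth inhibitor gene Cdkn1c fell from 4.58 to 1.16 FPKM, and the receptor gene Igf2r rose 2.87-fold to 17.2 FPKM in the authors' deposited table. The list's median of -0.15 did not differ from level-matched lists (permutation p = 0.648, adjusted p = 0.802).

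Lists around nucleic acid methylation and retrotransposon silencing were examined next. Of 22 tested genes of the AlkB family and of adenine methylation, 9 were called lower and none higher, and 7 were lower when adjusted over the list alone. N6amt2 fell from 99.2 to 35.3 FPKM and N6amt1, a methyltransferase gene, from 13.2 to 6.63 FPKM in the authors' deposited table. What the proteins of these 2 genes methylate was not tested. The list's median of -0.35 did not differ from level-matched lists (permutation p = 0.346, adjusted p = 0.53) and turned to 0.02 after recentring on abundant genes. Of 18 genes of cytosine methylation and demethylation, 5 were lower (Gadd45a, Dnmt3a, Mbd3, Dnmt3b and Dnmt3l) and 4 higher (Tet3, Tet2, Gadd45b and Dnmt1), the same when adjusted over the list alone. The de novo methyltransferase gene Dnmt3a fell from 27.0 to 13.9 FPKM, while the maintenance gene Dnmt1 rose from 38.2 to 58.0 FPKM in the authors' deposited table. Of 25 genes listed as retrotransposon silencing factors, 8 were lower and 1 higher (Dnmt1), also when adjusted over the list alone. The lower genes were led by L1td1, which is also on the naive pluripotency list, and Cbx3. Neither of these 2 lists passed against level-matched lists (permutation p = 0.295 and 0.0942, adjusted p = 0.512 and 0.232).

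Genes of basic cell functions fell as measured by about as much as level-matched lists. The width of the highest decile limits this comparison too, as for Pou5f1. Of 40 nuclear genes of the respiratory chain, 38 were called lower (40 when adjusted over the list alone), with a median of -0.69 that lay 0.03 above level-matched lists (permutation p = 0.625). Of 44 ribosomal protein genes, 40 were lower (41 when adjusted over the list alone), with a median of -0.71, equal to that of level-matched lists (permutation p = 0.946). Sdhd fell from 268 to 113 FPKM and Rpl14 from 1465 to 723 FPKM in the authors' deposited table. Uncalled were Atp5d and Sdhc in the former list and Rpl30, Rps15, Rplp0 and Rpl34 in the latter. Of 31 cell cycle genes, 17 were lower and 1 higher (Rb1), and 18 and 1 when adjusted over the list alone (permutation p = 0.238 for the median). The cyclin gene Ccnd2 fell from 2.27 to 0.440 FPKM in the authors' deposited table. Of 15 heat shock and chaperone genes, 10 were lower, also when adjusted over the list alone, with Hspe1 and Dnaja1 leading (permutation p = 0.748). Of 29 genes of the integrated stress response, 10 were lower and 2 higher (Pycr1 and Sesn2), and 9 and 2 when adjusted over the list alone (permutation p = 0.137). Atf4, the transcription factor of that response, fell from 363 to 183 FPKM in the authors' deposited table. The adjusted p of these 5 lists ranged from 0.274 to 0.961.

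Histone genes were low against genes of like level, though nearly all were uncalled. Of 13 tested replication-dependent histone genes, 1 (Hist1h2bc) was called lower, from 9.46 to 4.18 FPKM in the authors' deposited table, likewise when adjusted over the list alone. The list's median was -0.83, which was 1.36 below level-matched lists (permutation p = 0.0001, the smallest possible, adjusted p = 0.0009), and the difference shrank to -0.50 with a pseudocount of 1. Fewer than 3 of the 13 reached the 25th percentile of level (2.02 FPKM), so the filter on low genes gave no value for this list. These transcripts mostly lack a poly(A) tail, which a messenger RNA library selects for, and their copies share sequence.

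Counts of called members were also set against all other tested genes, which leaves the trend with level in the comparison. Higher calls were more frequent among hypoxia and glycolysis genes (odds ratio 6.60, Fisher's exact two-sided p = 8e-07, adjusted p = 2e-05), but p53 targets did not pass (1.95, p = 0.145). Lower calls were more frequent among respiratory chain (odds ratio 48.4) and ribosomal protein genes (25.5), with Fisher's exact adjusted p of 2e-17 and 6e-17. They were also more frequent among primed epiblast, heat shock, FGF and ERK, X-linked germline, naive pluripotency and cell cycle genes, with odds ratios from 3.07 to 6.32 (Fisher's exact adjusted p from 0.00748 to 0.00854). The BMP, Nodal and TGF-beta list (odds ratio 2.78, Fisher's exact adjusted p = 0.0669), neuroectoderm (2.53, adjusted p = 0.224) and histones (0.21, adjusted p = 0.236), whose medians passed, did not pass for lower calls.

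Genes of the X chromosome were called lower more often, and higher less often, than autosomal genes. Of 515 tested X genes, 183 (35.5%) were lower and 70 (13.6%) higher, against 28.1% and 22.8% of 13575 autosomal genes (odds ratio 1.41, Fisher's exact two-sided p = 0.0003 for lower and 0.53, p = 3e-07, for higher). Glod5 fell from 34.5 to 10.1 FPKM and Ptchd1 from 1.15 to 0.311 FPKM in the authors' deposited table, while Capn6 rose from 0.191 to 1.02 FPKM and Shroom4 from 0.133 to 0.637 FPKM. The median of X genes differed by -0.21 from that of level-matched sets (permutation p = 0.0001, adjusted over 20 chromosomes p = 0.0007), and the difference was -0.08 after matching also on transcript length and GC content (permutation p = 0.0115, adjusted p = 0.046). With 1 gene kept from each run of called neighbours, the odds ratio for lower genes was 1.22 (Fisher's exact p = 0.0785).

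Other chromosomes differed from matched genes by amounts of the same order. After matching on level, length and GC content, the genes of chromosome 11 lay 0.14 above their matched sets (adjusted permutation p = 0.001) and those of chromosome 1 lay 0.09 above (adjusted p = 0.002). Those of chromosome 9 differed by -0.11 (adjusted permutation p = 0.001) and those of chromosome 13 by -0.10 (adjusted p = 0.0195). The matching on level alone, which was fixed in advance, also called chromosomes 8 and 15, and these 2 were not called after the wider matching. By counts, chromosomes 3, 13 and 14 also had fewer higher calls (17.3%, 16.9% and 17.2%), and chromosome 9 more lower calls (33.6%). Chromosomes 7 and 11 had fewer lower calls (24.5% and 24.7%), and chromosome 11 more higher calls (27.2%). Fisher's exact p adjusted over chromosomes was at most 0.0163 for these, and 0.00661 (lower) and 6e-06 (higher) for X.

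**Figure D3:**
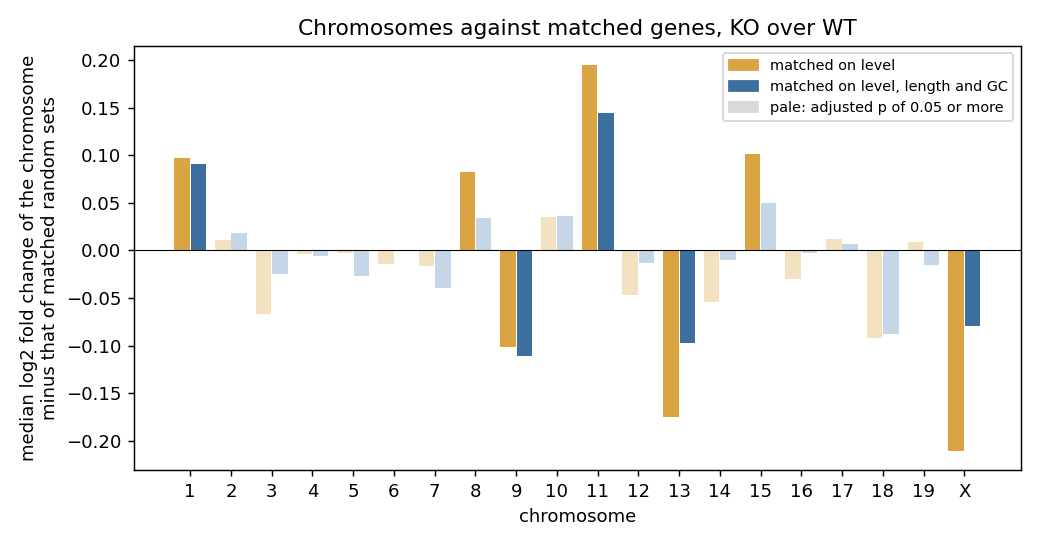
Bars give, for each of the 20 chromosomes compared, the median log2 fold change (KO over WT) of its tested genes minus the mean median of 10000 random gene sets, matched on level (yellow) or on level, transcript length and GC content (blue); pale bars did not pass an adjusted p of 0.05. The X bar goes from -0.21 to -0.08 with the wider matching, at which chromosomes 1 and 11 stay above and 9 and 13 below their matched sets.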

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

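Matching on length and GC content, leaving out small RNA genes, leaving out the X-linked germline list, leaving Btg2 out of the p53 targets, recentring within deciles and scaling to equal totals were chosen after the data were seen; the other alternatives were not. No paired analysis was possible because the deposited table holds 1 pooled value per condition, and for the same reason alternatives that need values per library, although set in advance, were not run (other normalizations, tests, filters and pseudocounts on libraries, the replicate block, 1 value per clone, leaving out each library, and set tests with an estimated correlation). The depth is unknown, so precision at low levels cannot be stated. The 7163 called genes became 2030 with a 2-fold threshold (1274 higher and 756 lower), and 1721 rather than 3163 were higher with genes under the 25th percentile of level left out; other totals stayed between 5484 and 8062, other counts of higher genes between 2428 and 3578, and other counts of lower genes between 3191 and 4484. The share of lower genes, 55.8%, turned to 37.2% at a 2-fold threshold, to 48.3% after recentring within deciles and to 33.2% with equal totals of tested genes, and was 55.6% or 56.8% at other q thresholds. It was 55.2% after recentring on abundant genes, which says little, since the calls were kept and few called genes lie that close to 0. Alkbh1 itself was at -0.87 with a pseudocount. Of the 8 lists past the threshold, 4 were past it without the least expressed genes and 7 to 8 otherwise. Hypoxia and glycolysis, p53 targets, and FGF and ERK targets passed in every setting run. Histones passed in those that gave them a value (-0.50 with a pseudocount, against -1.36). The filter on the least expressed members left too few histone genes to test. Calls ended without the least expressed members for primed epiblast (-0.48), neuroectoderm (-0.17) and BMP, Nodal and TGF-beta (-0.28, and -0.30 with a pseudocount), and with length and GC matching for X-linked germline clusters (-0.38), whereas methylation-silenced germline genes gained one (0.41). Lists not called in any setting changed sign as follows. With length and GC matching, naive pluripotency moved to -0.018 and 2-cell-like genes to 0.068. With means, trophoblast moved to -0.047, cytosine methylation to -0.078 and respiratory chain to -0.0091. Without the least expressed members, 2-cell-like genes moved to 0.0050, trophoblast to -0.19, imprinted genes to 0.0055 and heat shock to 0.060. With a pseudocount, mesoderm moved to 0.0026 and heat shock to 0.072. Without the least expressed members, 3 lists had too few genes for a value. The odds ratio for lower X genes, 1.41, was 1.22 and past the threshold no more with 1 gene per run of called neighbours (Fisher's exact p = 0.0785), and 1.27 to 1.73 otherwise; the odds ratio for higher X genes stayed between 0.52 and 0.62. The cause of these changes was not tested.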

Other observations

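The gene families, the windows along chromosomes and the tests of the 3 patterns below were chosen after the data were seen, except for the comparison of X genes with sets of the same level, which was fixed in advance. Among 62 families formed from symbol roots, 2 differed from genes matched on level, transcript length and GC content, both downwards. Of 48 genes of the large subunit of the mitochondrial ribosome (Mrpl), 46 were called lower in the authors' deposited table and none higher, with a median log2 fold change of -0.90 that differed by -0.31 from matched genes (permutation p = 0.0001, the smallest possible, adjusted p = 0.0031). This matching has 5 level bins in place of 10. The 2 highest deciles by level had medians of -0.51 and -0.72, so part of such a difference may be left over from level. The small subunit (Mrps) had 28 of 29 genes called lower in the authors' deposited table, with a median of -0.79 that differed by -0.18 from matched genes and did not pass (permutation p = 0.0397, adjusted p = 0.224). The cytosolic ribosomal proteins differed by -0.04 from such genes (permutation p = 0.489), and the respiratory chain by 0.03 (permutation p = 0.62). Of 326 zinc finger genes named Zfp, 99 were lower and 32 higher, with a median of -0.20 that differed by -0.23 from matched genes (permutation p = 0.0001, adjusted p = 0.0031), while recentring on abundant genes turned that median to 0.17.

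The fall of fold changes with expression level was the broadest pattern. The lowest and the highest decile differed by 1.41 in their medians (95% bootstrap interval 1.36 to 1.47). One scaling factor for all genes leaves that difference as it is if the deciles are kept, and deciles from rescaled values were not tried. Removal of length and GC content left 1.09 of that difference (1.01 to 1.17). Both were those of the longest annotated transcript, which may not be the one expressed. Their share may thus be larger than this removal shows. Fold changes also rose with these 2 properties themselves. After removal of level, medians were -0.20 in the shortest and 0.32 in the longest decile by transcript length. From the lowest to the highest decile by GC content, medians went from -0.35 to 0.20 (-0.23 and 0.12 after removal of level). An even background of reads in KO would add the same amount to every gene, yet after scaling the amount left over was 7.25 times as large in the fifth decile as in the lowest (6.85 to 7.69). A difference in library preparation or RNA quality, the authors' scaling combined with such a difference, and an effect of the knockout may each remain, and pooled values cannot separate them.

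X genes were lower than other genes. Expression level was not the whole cause, as X genes differed by -0.21 from sets of the same level (permutation p = 0.0001, the smallest possible). Matching on length and GC content as well left -0.080 (permutation p = 0.0115), so a large part of the difference went with these properties, and without the germline clusters -0.069 was left (permutation p = 0.0324). Chromosomes 9 and 13 differed from matched genes by -0.11 and -0.10, so a difference of this size is not particular to X. An effect of the knockout on X genes is a possible explanation for the remainder and was not tested apart from differences between the cell clones.

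Genes of a distal segment of chromosome 1 (133181827 to 137648806, mm9) were higher, among them Mdm4, Btg2, Elf3 and Kdm5b, with log2 fold changes of 1.72, 1.20, 0.87 and 0.59 in the authors' deposited table. These 4 were picked after their values were seen; of the 60 genes of the segment, 36 were called higher, 7 lower and the others not called. The 60 genes from Srgap2 to Csrp1 had a median of 0.48 after removal of level, length and GC content. That lies above the highest window median of 0.36 in 100 shuffles of gene positions. It argues against these properties, as taken from the longest transcript, as the whole cause. A window on chromosome 11 also exceeded the highest shuffled median, at 0.42. The window was picked by its median. Its many higher calls and the 81.7% of its genes above the median of their class therefore follow from that choice. Neither decides whether a few genes make the pattern. A copy number gain stays open: 1 extra copy in 25% to 100% of the cells would shift the segment by 0.17 to 0.58, and its median was 0.48 after the removal but 0.73 as measured, while that of its 28 abundant genes was 0.41 (95% bootstrap interval 0.07 to 0.74, which leaves out the choice of window) and 0.08. A regional effect of the knockout and a difference between clones stay open too, untested without values per library.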
